A study of Homo sapiens with 4 samples.

How the data were processed

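RNA that co-purified with V5-tagged KIF5A was sequenced from SK-N-AS cells, an established human neuroblastoma line. The cells had been transfected, a day before harvest, with a construct for wild-type (WT) KIF5A or for the mutant that the labels call d27. V5 is a short peptide tag that antibody-coated magnetic beads bind. Each construct had 2 immunoprecipitations, numbered 1 and 2 in the labels. Nothing in the labels says whether these came from separate cultures, so p-values of single genes measure only the spread between these libraries, which may be technical. No input, mock-precipitated or untransfected library is used here, so every value is a comparison of d27 with WT precipitates and none is an enrichment over background.

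Per the labels' protocols, RNA was extracted with Trizol, depleted of ribosomal RNA and made into libraries with a strand-marking kit, with the fragmentation time set for each sample by its RNA integrity. The depletion also targets the mitochondrial 12S ribosomal RNA, the product of MT-RNR1. Per the submitters' processing notes, reads were counted with HTSeq on GRCh38, and DESeq2 was also used. The aligner, the annotation release, the strand setting of the counting and all versions are not given in the sources used here. The deposited values are raw read counts per gene, under versioned Ensembl gene identifiers, with 1 table per library. HTSeq's summary entries (reads with no gene, ambiguous reads and reads aligned to several places; those for low quality and unaligned reads held 0) were left out of library sizes and tests. They held 47.6% and 47.3% of all entries in WT replicates 1 and 2 and 25.9% and 36.8% in d27 replicates 1 and 2. HTSeq leaves out reads that align to several places or overlap several genes, so genes with near-identical copies (histones, ribosomal proteins, RN7SL1, HSPA6, PCDHA9) can be undercounted to an unknown extent. Without the strand setting, reads of overlapping genes on opposite strands may not be told apart.

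The tables listed 60719 genes. Of these, 58488 had an entry in GENCODE release 29 (GRCh38) after version numbers were removed. That release gave gene types, positions, lengths and GC content. Symbols came from a table of gene names. Totals over genes were 8142869 and 10811134 counts for WT and 18335151 and 10483082 for d27, replicates 1 and 2. A count of 0 allows up to 3 counts, which is 0.368, 0.277, 0.164 and 0.286 CPM (counts scaled to the library total in the usual way) in the same order. A fold against a group with no counts is a bound against 3 counts over the group. Intervals and this floor cover counting error only, since reads carried no molecular identifiers.

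The main test was edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr by group (minimum count 10, minimum total 15), which left 14909 genes, and glmQLFit (robust) with glmQLFTest on group alone. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Fold changes are d27 over WT, and each standard error (SE) is the log2 fold change divided by the square root of the F statistic. CPM values in the text are scaled by TMM, except shares of the total. The 30 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the 29 lists with at least 5 tested members. Shares of counts were compared by an exact permutation test, which for 2 against 2 libraries cannot give a p below 0.333.

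The test was tried on counts simulated from these libraries, with 14241 genes tested in the simulated d27 against WT comparison. It recovered 32.8% of 2-fold, 86.6% of 4-fold and 95.5% of 8-fold changes and called 4 unchanged genes. Changes were placed only in genes above a minimum mean CPM, so these shares do not cover genes with few counts. The spread of each gene was set to the trend fitted across genes, with no batch, so the number of unchanged genes called depends on that model. A simulated list shifted by 0.8 on the log2 scale had a camera adjusted p of 1.31e-27 with the preset correlation. With an estimated correlation it had an adjusted p of 0.261, and with fry 0.0948, so those tests missed a simulated shift at this sample size. The simulated genes varied independently of each other, a setting that favours the preset correlation.

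The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule names KIF5A; up to 8 genes per direction with the largest called change, non-overlapping groups, at least 50 counts in each library of the higher group, a symbol and a protein-coding or lncRNA type; up to 3 called members of each list by lowest p, with at least 2 members by lowest p where a list's camera test passed; and the 10 most abundant genes. Some genes that the rule or a list count would name are not reported here. Alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals alone, no filter, at least 50 counts in 2 libraries, the replicate number as a block, an offset for GC content and exon length (mgcv 1.9.3), protein-coding genes only, totals without KIF5A and mitochondrial genes, and leaving out each library. List tests were repeated under the same settings except DESeq2. With the replicate block or a library left out, little spread between libraries remains to estimate a correlation from. The estimated-correlation test could hardly pass there, so its failures under those settings do not count against a list. Thinning all libraries to the lowest total, and an offset for GC, coding length and 3' UTR length, were added after seeing the data.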

Results

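The series asked which RNAs co-purify with KIF5A, a heavy chain of the kinesin-1 motor that carries cargo along neuronal microtubules, and how they differ between the wild-type protein and the d27 mutant, which its title groups with mutations linked to amyotrophic lateral sclerosis (ALS). RNA was sequenced from 2 anti-V5 precipitates of each construct. Gene counts totalled 8142869 and 10811134 in WT replicates 1 and 2 and 18335151 and 10483082 in d27 replicates 1 and 2. Between 19369 and 26305 genes had at least 1 count per library. The d27 libraries resembled each other (Pearson r = 0.963 across genes on the log2 CPM scale) more than the WT libraries did (r = 0.928), and WT replicate 2 stood farthest from the d27 libraries (r = 0.866 and 0.887). WT replicate 1 was as close to d27 replicate 2 (r = 0.930) as to WT replicate 2, and had r = 0.918 with d27 replicate 1. The libraries therefore did not group cleanly by construct. Replicates within a group differed by far more than counting noise, with a chi-square per degree of freedom of 53.3 in WT and 35.6 in d27.

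KIF5A itself was the most abundant transcript in every library and did not pass the test between groups. The gene (ENSG00000155980.13, GRCh38 chromosome 12, 57549998 to 57586632, plus strand) took 9.03% and 14.8% of gene counts in WT and 10.8% and 11.2% in d27, with exact binomial 95% intervals of 9.01% to 9.05%, 14.8% to 14.8%, 10.8% to 10.9% and 11.2% to 11.2%. Its log2 fold change was -0.20 ± 0.49 (SE; edgeR adjusted p = 0.821, n = 2 per group), and it changed sign to 0.40 without WT replicate 2. A count per gene adds transfected and endogenous transcripts and does not tell the constructs apart, so it is no check of which construct a library held. After KIF5A, the most abundant transcripts by mean over the 4 libraries were ACTB (cytoplasmic actin), the nuclear lncRNA MALAT1, the mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1, the large scaffold mRNAs AHNAK, PLEC, MAP1B and SPTBN1, and RPLP0. Their order differed between libraries: MALAT1 exceeded ACTB in both WT libraries and ACTB exceeded MALAT1 in both d27 libraries. Of these, AHNAK (log2 fold change -1.43), PLEC (-1.67), SPTBN1 (-1.63) and RPLP0 (-1.75) were lower in d27. The AHNAK, PLEC, SPTBN1 and RPLP0 calls were lost without d27 replicate 1, those of AHNAK, SPTBN1 and RPLP0 also without WT replicate 2, and those of AHNAK, PLEC and RPLP0 also without d27 replicate 2. The AHNAK and SPTBN1 calls were also lost with an offset for GC and exon length (adjusted p = 0.0800 and 0.0570), and those of AHNAK, PLEC and SPTBN1 with one for GC, coding length and 3' UTR length. ACTB (0.77 ± 0.33, adjusted p = 0.159) and MALAT1 (-1.20 ± 0.34, adjusted p = 0.0602) did not pass the edgeR test.

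The RNA recovered with d27 differed from that recovered with WT in 1743 of 14909 genes tested, of which 1192 were higher in d27 and 551 lower. Of the 8 genes with the largest rises, FOSB, EGR1 and FOS encode transcription factors that cells switch on quickly after a stimulus, and ATF3 encodes a stress-induced one. FOSB (chromosome 19, 45467995 to 45475179) went from 2.71 ± 0.29 CPM in WT to 429 ± 19 in d27 (SD, n = 2 each), a 158-fold difference (log2 7.30 ± 0.32 SE, edgeR adjusted p = 0.000233). EGR1 (chromosome 5, 138465490 to 138469315) went from 86.6 ± 10.3 to 3711 ± 236 CPM, 42.9-fold (log2 5.42 ± 0.34, edgeR adjusted p = 0.00225). FOS rose 28.3-fold and ATF3 18.6-fold, both with an edgeR adjusted p of 0.00226. All 4 passed edgeR with each library left out in turn. FOSB overlaps ERCC1 on the opposite strand.

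The other genes in the set with the largest rises had few or no counts in WT. FOXJ1, a transcription factor of ciliated cells (chromosome 17, 76136333 to 76141299), had 0 counts in both WT libraries and 867 and 924 in d27, at least 377-fold higher against a floor of 3 counts over the WT group. TPPP, a tubulin-polymerization promoter, had 2 counts over both WT libraries against 438 in d27, a ratio of 138 with a counting interval of 38.1 to 1146, and overlaps CEP72 on the opposite strand. EPHA1, an ephrin receptor, had 1 against 104 counts (ratio 65.7, interval 11.5 to 2620) and shares its locus with the opposite-strand gene ZYX. ZNF296 had 17 against 542 counts, with all 17 in WT replicate 1. The EPHA1 call was lost without d27 replicate 2, and the ZNF296 call without d27 replicate 1 and with DESeq2 (log2 4.31, adjusted p = 0.172).

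**Figure D1:**
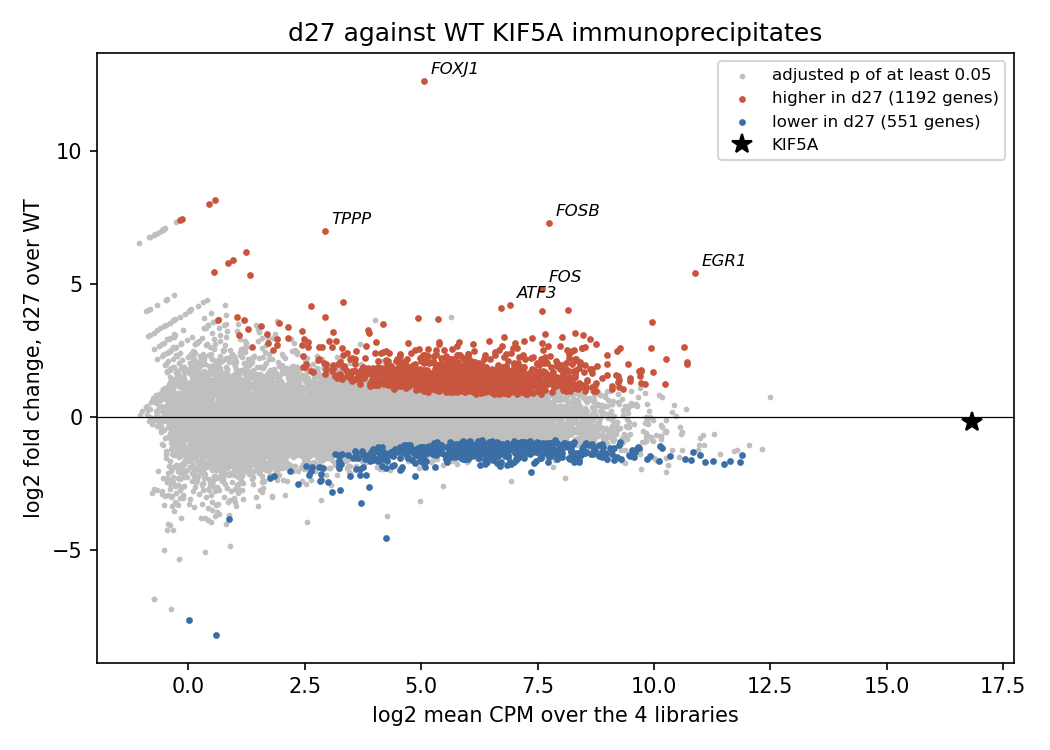
Log2 fold change (d27 over WT, vertical axis) against log2 mean CPM over the 4 libraries (horizontal axis) for 14909 genes; coloured points have an edgeR adjusted p under 0.05. FOXJ1, drawn at its fitted value against 0 WT counts, FOSB (7.30), TPPP, EGR1 (5.42), FOS (4.82) and ATF3 (4.22) are named, and KIF5A (star) lies at -0.20 at the highest abundance.

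Among protein-coding and lncRNA genes with a symbol and at least 50 counts in each WT library, the 8 called genes with the largest drops had log2 fold changes between -2.38 and -1.86. They were PCDHA9, a neuronal protocadherin (log2 fold change -2.38 ± 0.56 SE), MT-ND6, a mitochondrially encoded respiratory chain subunit (-2.06 ± 0.33), MLPH, a myosin adaptor (-2.04 ± 0.52), FREM1 (-1.93 ± 0.50), PIDD1 (-1.92 ± 0.36), the endosomal kinesin KIF16B (-1.87 ± 0.46), SPAG7 (-1.87 ± 0.35) and GOLGA8A (-1.86 ± 0.47). PCDHA9 shares exons with other protocadherin genes, and PIDD1 overlaps RPLP2 on the opposite strand, so both counts are uncertain. Among called genes, 1645 were protein-coding and 33 were lncRNAs. Both d27 libraries lay on the same side of both WT libraries in 9125 of the 14909 tested genes, a separation that chance gives 33.3% of genes. Genes of a library can shift together, so a share above that does not show a difference beyond chance. The 1743 calls became 768 without d27 replicate 1 (697 higher, 71 lower) and 4851 without WT replicate 1 (2715 higher, 2136 lower), and without WT replicate 2 the lower calls became 309. The calls of PCDHA9, MLPH, FREM1, KIF16B and GOLGA8A were each lost without d27 replicate 1 and without WT replicate 2, and that of MLPH also without d27 replicate 2. With library totals in place of TMM, MLPH and FREM1 did not pass (adjusted p = 0.0533 and 0.0591), nor did FREM1 with the GC and exon-length offset (0.0645), or FREM1 and KIF16B with the coding-length offset (0.141 and 0.0578).

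Several stress-response mRNAs were higher in d27. In the list for the unfolded protein and integrated stress response, 5 of 27 tested members rose, 1 fell and 21 did not pass (6 rose and 1 fell when adjusted over the list alone). Besides ATF3, PPP1R15A, a phosphatase subunit that reverses translational arrest, rose from 274 ± 30 to 1674 ± 6 CPM (log2 2.61 ± 0.28 SE, edgeR adjusted p = 0.0068), and ATF4, the main transcription factor of the integrated stress response, rose from 169 ± 39 to 846 ± 13 CPM (log2 2.32 ± 0.28, adjusted p = 0.00726). The others, chosen after their values were seen, were SESN2 (2.38) and XBP1 (1.58), which rose, and HSPA5, a chaperone of the endoplasmic reticulum, which fell (-1.06). The list as a whole was higher by camera (adjusted p = 0.00548), with adjusted p = 0.551 with an estimated correlation. Its median log2 fold change of 0.17 became 0.38 without WT replicate 1, 0.055 without WT replicate 2, 0.33 without d27 replicate 1 and 0.26 without d27 replicate 2, which spans the range over 15 alternatives.

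Among 18 heat shock chaperones, 4 rose and 14 did not pass, both over all genes and adjusted over the list alone. The cochaperone DNAJB1 rose from 102 ± 25 to 628 ± 91 CPM (log2 2.62 ± 0.29 SE), and the cochaperone BAG3, which links HSP70 to autophagy, from 92.4 ± 25.9 to 513 ± 10 CPM (2.47 ± 0.29), with edgeR adjusted p-values of 0.00684 and 0.00691. HSPA6, a strictly heat-inducible HSP70, rose from 19 counts over both WT libraries to 381 in d27 (log2 3.76 ± 0.52, edgeR adjusted p = 0.00991), and DNAJB6, chosen after its value was seen, also rose (1.33). The list did not pass camera (adjusted p = 0.0903), but passed without d27 replicate 1 (adjusted p = 0.0402, with a range of 0.0109 to 0.179 over 15 alternatives, and adjusted p = 0.731 with an estimated correlation). Of 26 autophagy and lysosome genes, MAP1LC3B, which encodes an autophagosome marker, rose (log2 2.02 ± 0.29), as did the autophagy receptor OPTN (1.25 ± 0.23), and 24 did not pass (camera adjusted p = 0.678). The same 2 rose when adjusted over the list alone.

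**Figure D2:**
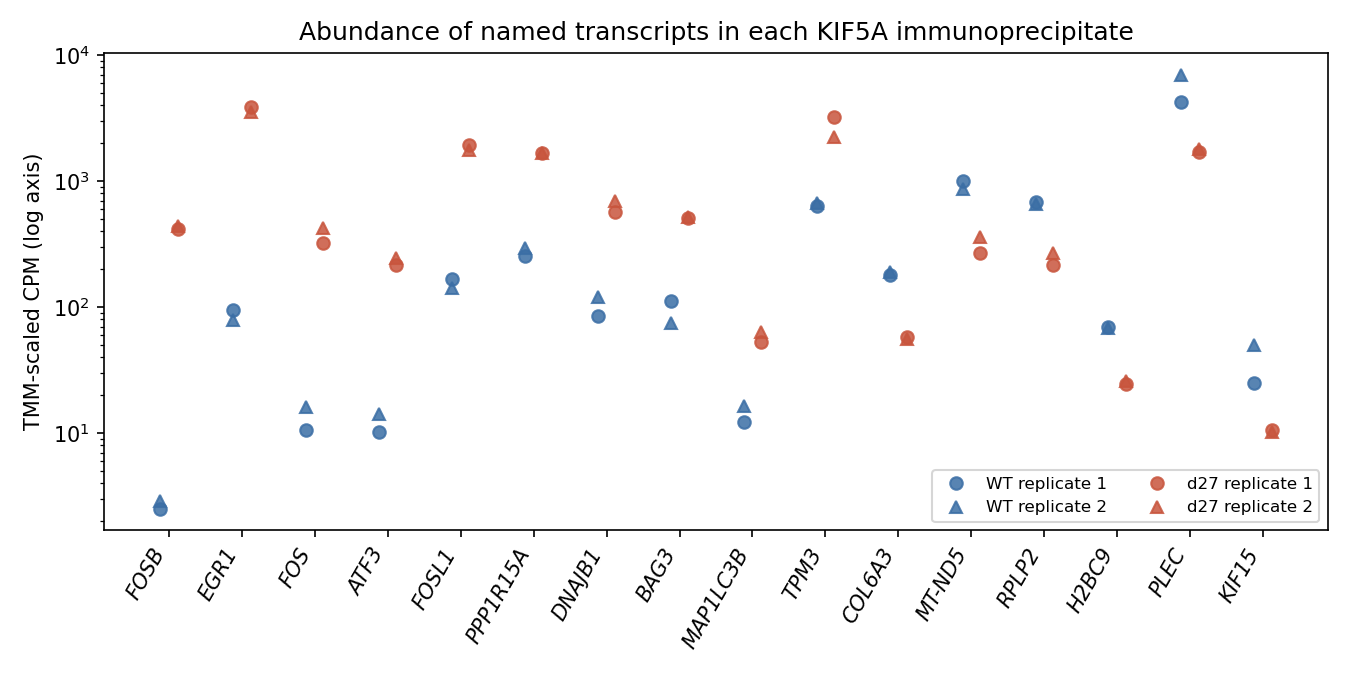
TMM-scaled CPM (log axis) of 16 named transcripts in each library; circles are replicate 1 and triangles replicate 2, blue WT and red d27. FOSB to TPM3 lie higher in both d27 libraries than in both WT libraries, and COL6A3 to KIF15 lie lower.

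Of 27 mRNAs known to localise to axons or dendrites, 7 rose, 1 fell and 19 did not pass (8 and 2 adjusted over the list alone; camera adjusted p = 0.159). BCL2L2, a survival factor, rose from 21.6 ± 0.8 to 73.0 ± 3.8 CPM, NRN1, a neurite growth factor, from 28.6 ± 0.9 to 93.1 ± 12.0 CPM, and DLG4, the postsynaptic scaffold PSD-95, from 29.3 ± 5.7 to 101 ± 8 CPM, with log2 fold changes of 1.75, 1.70 and 1.78 and edgeR adjusted p-values of 0.0103, 0.0109 and 0.0109. The 1 that fell was again HSPA5. DLG4 overlaps the opposite-strand gene ACADVL and BCL2L2 overlaps HOMEZ. Among 26 proteins of RNA granules reported with KIF5, the mRNAs of FXR2 (log2 1.42) and SYNCRIP (1.09) rose and that of the helicase DHX9 fell (408 ± 2 to 204 ± 19 CPM), while 23 did not pass (camera adjusted p = 0.438; 2 higher and 1 lower adjusted over the list alone). Of 24 synaptic genes, DLG4 and SYN1 (log2 2.93 ± 0.63) rose and UNC13A (-0.98 ± 0.26) fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.254). SYN1 had 16 counts over both WT libraries and overlaps ARAF and TIMP1 on the other strand. Without d27 replicate 1 the calls of SYNCRIP, DHX9, SYN1 and UNC13A were lost, as were those of SYNCRIP, DHX9 and UNC13A without WT replicate 2 and of DHX9 and UNC13A without d27 replicate 2. DHX9 did not pass with library totals only (adjusted p = 0.0591) or with the coding-length offset (log2 -0.08, adjusted p = 0.811).

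Genes encoding the motor machinery showed no common rise. Of 6 kinesin-1 chains, the light chain KLC2 rose (log2 1.09 ± 0.23 SE, edgeR adjusted p = 0.026) and 5 did not pass, in both adjustments (camera adjusted p = 0.618). Of 16 KIF5 cargo adaptors, ZFYVE27, which encodes protrudin, rose (1.40 ± 0.25) and HTT, which encodes huntingtin, fell (-1.29 ± 0.30), and 14 did not pass (1 and 2 adjusted over the list alone; camera adjusted p = 0.256). Of 29 other motors, 8 fell, none rose and 21 did not pass (13 fell adjusted over the list alone). These included the mitotic kinesins KIF11 (-1.39 ± 0.25), KIF14 (-1.28 ± 0.25) and KIF15 (-1.86 ± 0.38). The list was lower by camera (adjusted p = 5.38e-05), with adjusted p = 0.551 with an estimated correlation. With an offset for GC, coding length and 3' UTR length the list did not pass (adjusted p = 0.0619, the highest of 15 alternatives; the lowest was 4.18e-08). Of 32 ALS and frontotemporal dementia genes, OPTN, VAPB (0.87 ± 0.22) and ANXA11 (0.86 ± 0.22) rose, UNC13A fell and 28 did not pass (3 and 6 adjusted over the list alone; camera adjusted p = 0.229). The KLC2 call was lost without d27 replicate 1, the HTT call without that library or WT replicate 2, and the VAPB, ANXA11 and UNC13A calls without either of those or d27 replicate 2. With library totals only, VAPB, ANXA11 and UNC13A did not pass (adjusted p = 0.0596, 0.0669 and 0.0702), and with the GC and exon-length offset HTT (log2 -0.65, adjusted p = 0.0767) and UNC13A (-0.60, 0.0788) did not. With the coding-length offset HTT (-0.32, adjusted p = 0.289), UNC13A (-0.12, 0.723), VAPB (0.32) and KIF15 (adjusted p = 0.0634) did not pass.

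Mitochondrially encoded and histone mRNAs had the lowest medians of the tested lists. Of 13 mitochondrially encoded mRNAs, 9 fell and 4 did not pass, and the log2 fold change was below 0 for all 13, with a median of -1.40 (12 fell adjusted over the list alone). MT-ND6 fell from 267 ± 112 to 63.9 ± 8.3 CPM (log2 -2.06 ± 0.33 SE, edgeR adjusted p = 0.0141) and MT-ND5 from 931 ± 100 to 314 ± 61 CPM (-1.57 ± 0.28, adjusted p = 0.018). Of 27 replication-dependent histone genes, whose mRNAs lack poly(A) tails, 10 fell and 17 did not pass (21 fell adjusted over the list alone), with H2BC9 (-1.45 ± 0.25), H2AC13 (-1.46 ± 0.27) and H3C2 (-1.52 ± 0.30) the lowest in p. Both lists had a camera adjusted p of 6.13e-10, and both had adjusted p = 0.551 with an estimated correlation. The MT-ND5 call was lost without d27 replicate 1.

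Few ribosomal protein mRNAs passed singly. Of 46 large-subunit genes 5 fell and 41 did not pass (7 adjusted over the list alone), with a median log2 fold change of -0.65, which became -0.42 without d27 replicate 1. Of 33 small-subunit genes 1 fell, in both adjustments, with a median of -0.46, which became -0.73 without d27 replicate 2. Both lists were lower by camera (adjusted p = 5.84e-06 for the large and 0.000758 for the small subunit), with adjusted p = 0.636 and 0.659 with an estimated correlation. RPLP2 fell from 668 ± 11 to 240 ± 38 CPM, RPL19 from 1132 ± 109 to 501 ± 53, and RPLP0 from 4461 ± 2205 to 1331 ± 82. RPL13 (-0.92) and RPL23A (-0.95), chosen after their values were seen, also fell. In the small subunit FAU (-1.26 ± 0.23) fell, and RPS29 (-1.04 ± 0.29, edgeR adjusted p = 0.0543) did not pass. RPS29 overlaps the abundant RN7SL1 on the opposite strand. Of 48 nuclear-encoded respiratory chain genes, 6 fell and 42 did not pass (11 fell and 1 rose adjusted over the list alone), including COX5B (-1.46 ± 0.34), NDUFB4 (-1.66 ± 0.39) and NDUFV1 (-1.10 ± 0.26). Camera gave an adjusted p of 0.000972 for that list, with adjusted p = 0.659 with an estimated correlation, and the preset-correlation call was lost without WT replicate 1 (adjusted p = 0.0577, the highest of 15 alternatives; the lowest was 3.29e-07). The calls of RPLP2, RPL19, RPLP0, FAU, COX5B, NDUFB4 and NDUFV1 were lost without d27 replicate 1, those of RPLP0, COX5B and NDUFV1 also without WT replicate 2, and those of RPL19 and RPLP0 also without d27 replicate 2. With library totals only, RPL19, NDUFB4 and NDUFV1 did not pass (adjusted p = 0.0520, 0.0533 and 0.0624).

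Of 25 tested extracellular matrix genes, 12 fell, 1 rose and 12 did not pass (16 fell and 2 rose adjusted over the list alone). The list was lower by camera (adjusted p = 1.31e-05), with adjusted p = 0.551 with an estimated correlation, and its median log2 fold change of -0.97 became -0.42 with the offset for GC, coding length and 3' UTR length. COL6A3 fell from 184 ± 6 to 57.1 ± 1.3 CPM (log2 -1.69 ± 0.23 SE, edgeR adjusted p = 0.00904), FBN1 from 112 ± 7 to 46.5 ± 4.3 and COL4A2 from 71.3 ± 3.5 to 28.8 ± 1.3. Of 28 mitotic and replication genes, 5 fell, namely BUB1B (-1.22 ± 0.24), CCNB1 (-1.09 ± 0.23), MCM3 (-1.26 ± 0.26) and, chosen after their values were seen, MCM2 (-1.56) and TOP2A (-1.70). BIRC5 (1.10) and CCNE1 (1.23), chosen likewise, rose, and 21 did not pass (15 fell and 2 rose adjusted over the list alone). Of 30 nuclear pore and transport genes, 8 fell, among them NUP160 (-1.17 ± 0.26), TPR (-1.53 ± 0.36) and NUP133 (-1.03 ± 0.24), and 22 did not pass (12 fell and 1 rose adjusted over the list alone). The mitotic and nuclear transport lists had camera adjusted p-values of 5.68e-05 and 0.00296, and both had adjusted p = 0.551 with an estimated correlation. Without d27 replicate 1 the calls of COL4A2, BUB1B, CCNB1, MCM3, NUP160, TPR and NUP133 were lost, and MCM3, TPR and NUP133 also lost theirs without WT replicate 2, as did NUP133 without d27 replicate 2. COL4A2 did not pass with the GC and exon-length offset (log2 -0.68, adjusted p = 0.0868), nor NUP133 with library totals only (adjusted p = 0.0574). With the offset for GC, coding length and 3' UTR length, COL6A3 (-0.55, adjusted p = 0.200), FBN1 (-0.35, 0.308), COL4A2, BUB1B, NUP160, TPR and NUP133 did not pass, and neither did the nuclear transport list (camera adjusted p = 0.268, the highest of 15 alternatives; the lowest was 0.000199).

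Of 9 tested noncoding RNAs that stay in the nucleus or form ribonucleoproteins, RN7SL1, the RNA of the signal recognition particle, fell from 3337 ± 1100 to 1048 ± 258 CPM (log2 -1.67 ± 0.36 SE, edgeR adjusted p = 0.0293). The other 8 did not pass (3 fell adjusted over the list alone), among them NEAT1 (-1.24 ± 0.34, adjusted p = 0.0528), and all 9 had a log2 fold change below 0. The list had a camera adjusted p of 0.0012, with adjusted p = 0.551 with an estimated correlation. As a check on RNA from other cell types, 4 of 17 marker genes were abundant enough to test. The keratin KRT18 (186 ± 38 to 72.4 ± 2.5 CPM) and the leukocyte phosphatase PTPRC (176 ± 20 to 90.3 ± 14.9 CPM) fell, and 2 did not pass. KRT18 and PTPRC had counts in every library, and whether these came from SK-N-AS cells or from other cells was not tested. Separately, WT libraries held larger shares of reads assigned to no gene, 20.6% and 21.8% against 13.5% and 16.7% in d27. The RN7SL1 call was lost without d27 replicate 1, and the PTPRC call without any 1 of the 4 libraries, with library totals only (adjusted p = 0.0769) and with the coding-length offset (0.142).

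The remaining lists did not pass camera. Among 24 tubulin and actin genes, TPM3, a tropomyosin, rose from 648 ± 24 to 2726 ± 679 CPM, and TUBG1 (log2 -1.09) and ACTN1 (-1.60) fell. TUBA1B (1.24) rose and TUBB6 (-1.15) fell, both chosen after their values were seen. In that list 2 rose, 3 fell and 19 did not pass (2 and 4 adjusted over the list alone; camera adjusted p = 0.254). Of 18 intermediate filament and neuronal cytoskeleton genes, STMN1 (150 ± 47 to 425 ± 1 CPM) and STMN3 (log2 1.27) rose in both adjustments, with a list median of -0.20 and a mean of 0.05 (camera adjusted p = 0.96). Of 28 translation factors, EIF1 (1.90) and EIF1AX (1.47) rose in both adjustments (camera adjusted p = 0.96, with a median of -0.02 and a mean of 0.04). Of 21 cholesterol synthesis genes, MSMO1 (1.63) and INSIG1 (1.65) rose in both adjustments (camera adjusted p = 0.44, with a median of -0.00064 and a mean of 0.17). Of 18 glycolysis genes, PGAM1 (1.13) and LDHA (1.06) rose and PFKP (-1.33) fell, as did, chosen after their values were seen, GAPDH (-1.29) and PFKL (-1.36) (2 rose and 5 fell adjusted over the list alone; camera adjusted p = 0.166). Of 31 proteasome genes PSMB2 (1.29) rose and PSMD4 (-1.03) fell in both adjustments (camera adjusted p = 0.066). Of 30 splicing factors PRPF8 (-1.39) and SF3B1 (-0.97) fell (1 adjusted over the list alone; camera adjusted p = 0.181). Of 12 adrenergic neuroblastoma markers, 2 fell in both adjustments, among them DDC (-1.24), and 10 did not pass (camera adjusted p = 0.535). FOSL1 (3.57 ± 0.30) rose among 14 mesenchymal ones (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.43). None of 24 interferon genes passed edgeR over all genes or over the list alone (median 0.72, camera adjusted p = 0.181). With the preset correlation that list passed without WT replicate 2 (median 1.64, camera adjusted p = 3.76e-09) and without d27 replicate 1 (1.30, adjusted p = 2.59e-10), and its median was -0.31 without d27 replicate 2. With an estimated correlation its adjusted p was 0.862 with all libraries and 0.734 and 0.766 without those libraries.

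Without d27 replicate 1, the calls of TUBG1, ACTN1, PSMD4, PFKP, LDHA, PRPF8, SF3B1, EIF1AX and DDC were lost. Without WT replicate 2, those of TUBG1, ACTN1, STMN3, PSMB2, PGAM1, PFKP and LDHA were lost. Without d27 replicate 2, those of PSMD4, LDHA and SF3B1 were lost, and without WT replicate 1, that of SF3B1. With library totals only, PSMD4, LDHA, SF3B1 and DDC did not pass (adjusted p = 0.0525, 0.0611, 0.0805 and 0.0802), and with the coding-length offset STMN3, PFKP, LDHA, SF3B1 and PRPF8 did not. The proteasome list passed camera without WT replicate 2 and without d27 replicate 2 (adjusted p = 0.0353 and 0.0183, with a range of 0.00405 to 0.365 over 15 alternatives), and the glycolysis list without d27 replicate 2 (0.0229, with a range of 0.0229 to 0.707). With an estimated correlation these had adjusted p = 0.764 and 0.607 for the proteasome and 0.607 for glycolysis.

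**Figure D3:**
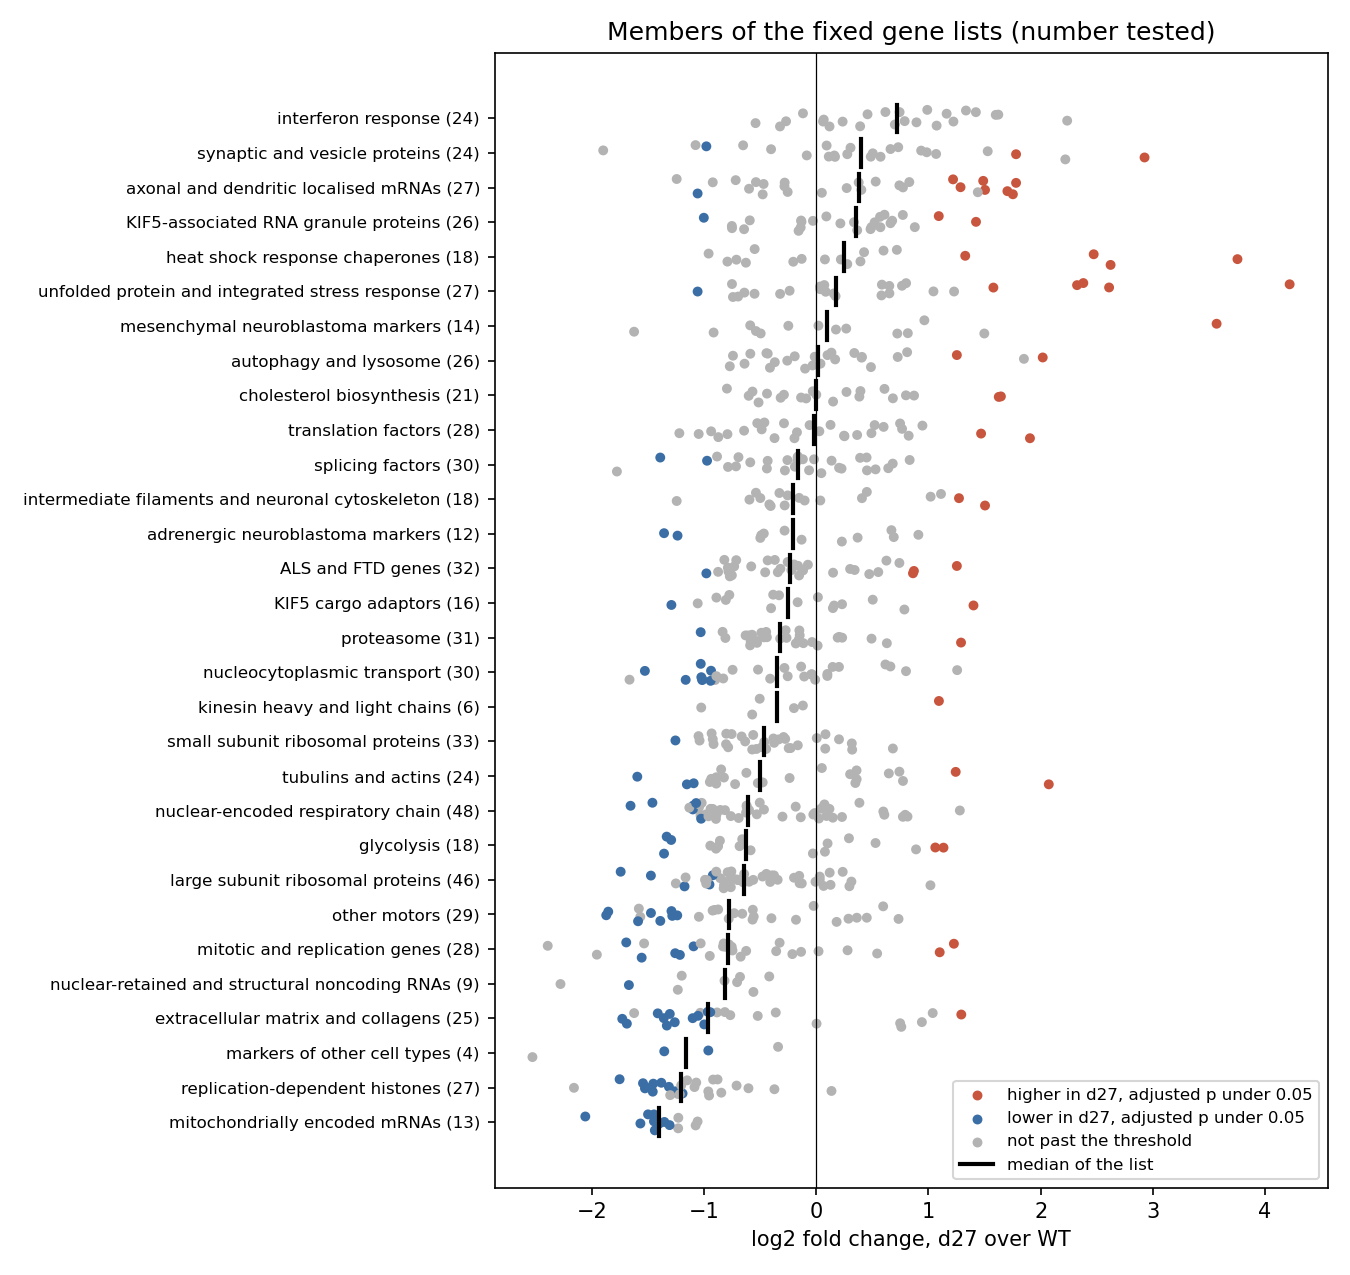
Log2 fold change (d27 over WT, horizontal axis) of each tested member of the 30 gene lists; black bars are list medians, red and blue points are members higher or lower with an edgeR adjusted p under 0.05, and grey points did not pass. Mitochondrially encoded mRNAs (median -1.40) and histones lie lowest, and ATF3 (4.22) and HSPA6 (3.76) lie farthest right in the stress and chaperone lists.

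The list calls made with the preset correlation numbered 11 of 29, 1 higher and 10 lower. None passed with an estimated correlation or with fry. Both also missed a simulated shift at this sample size, but the simulated genes varied independently. Correlations estimated for the 11 lists ranged from -0.014 (mitotic genes) to 0.787 (mitochondrially encoded mRNAs), with 0.493 for histones. For lists with high values, p-values at the preset 0.01 can be too small. At that setting camera takes its spread over genes, so for none of the 11 lists do its p-values measure the spread between libraries. With it, replicate 2 against replicate 1 gave calls for interferon genes (camera adjusted p = 1.49e-48) and histones (0.0155), where edgeR called 0 genes. Calls of all 11 lists therefore stay uncertain.

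By RNA class, d27 libraries held more protein-coding counts, 96.8% ± 0.8 against 94.3% ± 1.2 in WT (SD, n = 2 each). They held less of the mitochondrial genome, 0.838% ± 0.447 against 2.01% ± 0.94, less lncRNA, 1.34% ± 0.03 against 1.94% ± 0.06, and less small structural RNA, 0.399% ± 0.218 against 0.939% ± 0.146. The mitochondrial shares were 2.67% and 1.34% in WT and 0.522% and 1.15% in d27, replicates 1 and 2. They include the depletion target MT-RNR1, which was higher in d27 replicate 2 than in WT replicate 2 (3152 against 2589 CPM). A part of the depletion in these shares was not tested. Pseudogenes held 0.558% ± 0.136 in d27 and 0.7% ± 0.134 in WT (exact permutation p = 0.667). In each of the first 4 classes both d27 libraries lay beyond both WT libraries. The exact permutation p, with both tails counted, was 0.333 for each, the smallest that 2 against 2 libraries allow, so none can pass a threshold of 0.05.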

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

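Reads outside the gene counts, which no comparison used, were a large part of every library. Reads assigned to no annotated gene were 20.6% and 21.8% of entries in WT replicates 1 and 2 and 13.5% and 16.7% in d27 replicates 1 and 2. Reads aligned to more than 1 place were 23.7% and 22.8% in WT and 9.1% and 17.1% in d27. They are listed because they are a signal, above the limit that a count of 0 allows, in data outside the comparisons, and both shares were lower in each d27 library than in each WT library. No explanation was tested.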

How the results depend on the processing

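Thinning, the offset for GC, coding length and 3' UTR length, and estimated correlations under the alternatives were chosen after seeing the data. KIF5A did not pass under any of 16 alternatives. The 1743 calls became 2841 with DESeq2 (1118 lower), 2862 without a filter (1888 higher, 974 lower), 3575 with the replicate block (2137 higher, 1438 lower) and 3844 with the replicate block plus the GC and length offset (2248 higher, 1596 lower). The split moved from 1192 higher and 551 lower to 889 and 285 with library totals only, 1379 and 959 with at least 50 counts in 2 libraries and 1380 and 900 with protein-coding genes only. Leaving out each library gave 768 to 4851 calls, 697 to 2715 higher and 71 to 2136 lower; the lone library left in a group is assumed to vary like the other group. The higher share of calls was 68.4%, and 90.8% without d27 replicate 1 and 56.0% without WT replicate 1. Of the 1743, none changed sign under any scaling, filter, block or left-out library where it was tested, 1 did with the GC and length offset, with or without the block, and 25 of 1645 did with the coding-length offset. All 1743 had both d27 libraries on the same side of both WT libraries. Leaving out a library, the block or a mild rescaling could therefore hardly change a sign. Called lists fell from 11 to 0 with fry and to 0 with an estimated correlation. The medians of those lists are the same in all 3 tests: -0.78 for other motors, -0.65 and -0.46 for large and small ribosomal subunits, -1.40 for mitochondrially encoded mRNAs, -0.61 for the respiratory chain, -0.82 for noncoding RNAs, -1.21 for histones, 0.17 for the stress response, -0.97 for extracellular matrix, -0.79 for mitotic genes and -0.35 for nuclear transport. Without a filter, lists that had not passed camera did, with medians of 0.44 (axonal), 0.31 (heat shock), -0.25 (proteasome), 0.78 (interferon) and -0.56 (glycolysis); with an estimated correlation the lowest of their adjusted p-values was 0.406. So did interferon with the replicate block (0.68), the proteasome with the GC and length offset (-0.42) and with protein-coding genes only (-0.37), and, with the replicate block plus that offset, the proteasome (-0.41), interferon (0.55) and glycolysis (-0.54). With an estimated correlation these had adjusted p = 0.732, 0.609 and 0.724, and 0.719 for each of the last 3. With the coding-length offset, heat shock (0.32), proteasome (-0.42), tubulins and actins (-0.46), glycolysis (-0.35), splicing (-0.29) and adrenergic markers (-0.46) passed (lowest adjusted p = 0.350 with an estimated correlation), while other motors (-0.20) and nuclear transport (-0.14) did not. Leaving out 1 library moved the median of other motors to -0.39 (without WT replicate 2), noncoding RNAs to -1.29 and the small subunit to -0.73 (without d27 replicate 2), the large subunit to -0.42 (without d27 replicate 1) and the stress response to between 0.055 and 0.38. With a library left out, medians ranged from -0.71 to -0.33 for the respiratory chain, 0.042 to 0.47 for heat shock, -0.51 to -0.20 for the proteasome, -0.31 to 1.64 for interferon and -0.71 to -0.28 for glycolysis. Among named genes, 16 of 92 were no longer past the threshold with library totals only (adjusted p = 0.0520 for RPL19 to 0.0805 for SF3B1), 6 of 92 with the GC and exon-length offset (FREM1, HTT, UNC13A, COL4A2, AHNAK and SPTBN1) and 1 of 91 with DESeq2 (ZNF296). In the other direction, 5 of the 91 passed with DESeq2 that had not passed in edgeR. With the coding-length offset, 22 of 83 lost their call in the same direction, COL6A3, FBN1 and KIF15 among them, PRPF8 also lost its call and turned from -1.39 to 0.0019 on the log2 scale, and the median over shared genes moved by -0.13. Same-numbered libraries deviated from their group means with a correlation of 0.0962 across genes, and nothing in the labels ties the numbers to a shared day. Yet interferon-induced mRNAs were higher in replicate 2 of both constructs (MX1 at 57.4 and 103 CPM in WT and d27, against 4.44 and 20.7 in replicate 1). Whether same-numbered libraries shared a batch therefore stays open and untested. The block changed no call among named genes that had passed, and RPS29, NEAT1 and MALAT1 passed with it. Replicate 2 against 1 gave 0 genes in edgeR with group and number in the model (1646 at an unadjusted p under 0.05), 92 with library totals only, 312 without a filter and 250 with at least 50 counts in 2 libraries; DESeq2 was not run on it. The cause of these changes was not tested. The mitochondrial and noncoding lists have no value with protein-coding genes only. With 2 libraries per group, 32.8% of simulated 2-fold changes were recovered, with changes placed only in genes above a minimum mean CPM. Thinning to the lowest total gave 1875 calls, so calls were not fewer at lower depth.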

Other observations

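The regression on 3' UTR length was chosen after its result was seen, and the immediate-early list and its random lists, the thinning and the coding-length offset were chosen after the fold changes were seen; the other tests of explanations were chosen before their results. Immediate-early genes, the first to be transcribed after a stimulus, were higher in d27 well beyond the genes named above. Of 35 tested members of a textbook list compiled after the fold changes of FOSB, EGR1, FOS, ATF3, FOSL1, KLF4, ZFP36 and IER3 had been seen, 21 were higher, none was lower and 14 did not pass, and the log2 fold change was above 0 for 34. ZFP36, which encodes a protein that destabilises AU-rich mRNAs, went from 27.8 and 18.8 CPM in WT to 330 and 401 in d27 (log2 3.97 ± 0.31 SE, edgeR adjusted p = 0.00344). KLF4 (log2 2.75), JUND (2.67), SRF (1.95) and EGR3 (4.16) also rose. MYC (0.15 ± 0.26, adjusted p = 0.735) and IER5 (0.14 ± 0.24, adjusted p = 0.728) did not pass.

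Several interferon-induced mRNAs had higher values in replicate 2 of both constructs. MX1 stood at 4.44 and 20.7 CPM in replicate 1 of WT and d27 and at 57.4 and 103 in replicate 2, and OAS3 at 82.8 and 111 against 304 and 345. The list of 24 interferon genes was higher in replicate 2 in a model with group and number (median log2 difference 1.72, camera adjusted p = 1.49e-48 with the preset correlation and adjusted p = 0.945 with an estimated correlation), while MX1, OAS3, IFIT1 and IFIT3 each had an edgeR adjusted p of 0.0869. In the same contrast and with the preset correlation, cholesterol synthesis (adjusted p = 0.00124), glycolysis (0.00151) and noncoding RNAs (0.0332) were also higher in replicate 2, and histones (0.0155) and mesenchymal markers (0.0468) lower. With an estimated correlation these had adjusted p = 0.994 for histones and 0.945 for each of the others. With group and number both in the model, little spread between libraries is left to estimate a correlation from. Such a test could hardly pass, so these values neither uphold nor overturn the calls made with the preset correlation. With the replicate block the list also passed as higher in d27 with the preset correlation (camera adjusted p = 0.00769, with a range of 2.59e-10 to 0.768 over 15 alternatives), with adjusted p = 0.732 with an estimated correlation.

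Technical explanations were weighed for the 1743 calls as a whole. With the GC and exon-length offset, 1549 of them stayed past the threshold in the same direction, and with all libraries thinned to the lowest total 1707 did, which argues against a GC and exon-length trend or the depth of d27 replicate 1 as the whole cause. With the offset for GC, coding length and 3' UTR length 1036 of 1645 stayed, and the called genes kept a median of 0.693 of their log2 fold change, against 0.909 with the GC and exon-length offset. Without WT replicate 2, the library farthest from the rest, the called genes kept a median of 0.927 of their log2 fold change. These genes were selected with that library included, so the ratio cannot exclude a part of WT replicate 2 in the calls. Whether d27 binds other RNAs or the cells hold other RNAs stays open and untested, since no input library is used here.

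Across 12231 protein-coding genes, fold changes fell with coding length (Spearman rho = -0.404 across genes, which are not independent replicates). Beside 3' UTR length, the slope of log2 CPM per doubling of coding length differed between d27 and WT libraries by -0.321 ± 0.0793 (SE over libraries). That SE rests on 2 libraries per group. The median log2 fold change was 0.43 in the 2450 genes with the shortest coding sequences (467 higher, 34 lower) and -0.61 in the group with the longest (33 higher, 346 lower). GC content left 1.00 of the slope on coding length, and against WT replicate 1 alone rho was -0.344, so neither GC content nor WT replicate 2 is the whole cause, although the WT replicates also differed from each other along this trend (rho = 0.24). A bias by total transcript length would give 3' UTR length a negative slope, as coding length has. Beside coding length, the slope of log2 CPM per doubling of 3' UTR length was higher in d27 libraries by 0.10 ± 0.0552 (SE over libraries). In the 4 pairs of a WT and a d27 library this difference was 0.128, 0.173, 0.0271 and 0.0726. Between the d27 replicates (2 over 1) it was -0.101. For 3' UTR length alone, without coding length, rho was 0.240, 0.238, 0.0268 and 0.0933 in the same pairs but -0.393 between the d27 replicates. The d27 replicates thus differed about as much as the groups, and such a bias stays open. Over 1351 lncRNAs, which are not the genes of this trend, exon length gave a rho of -0.00752. A length effect of fragmentation, which was timed by each sample's RNA integrity, and a difference in what d27 and WT precipitates hold also stay open and untested.

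The immediate-early rise may be a feature of d27 precipitates beyond that trend. The list's median log2 fold change was 1.69, and 1.49 with the GC, coding-length and 3' UTR-length offset. Without the 8 members seen beforehand, 13 of 27 rose, and the median was 1.33 and, with the offset, 0.89, against highest medians of 0.89 and 0.71 among 10000 random lists of the same size and matched expression. The random lists were drawn gene by gene, whereas genes that respond to the same stimulus can vary together. They therefore do not show whether the rise belongs to d27 or to the cultures. With AUUUA density in the regression, the list's median residual was 1.44 against a median log2 fold change of 1.69. It includes the 8 members seen beforehand, whose large rises favour a high residual, and was not computed without them. It therefore cannot exclude AU-rich 3' UTRs as a class for the other members. The AUUUA slope was 0.007 ± 0.004 per motif per kilobase. That SE is over genes, which are not independent replicates, and does not measure the spread over libraries. Higher abundance of these mRNAs in d27-transfected cells, handling of the cultures, to which such genes respond, and association with d27 all stay open and untested.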
